A study of Caenorhabditis elegans with 4 samples.

How the data were processed

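Chromatin from Caenorhabditis elegans strain OP178 was analysed, from fed L1 hermaphrodites grown at 20 °C. The strain was made by bombardment and carries the transgene wgIs178, with skn-1 fused to TY1, EGFP and FLAG tags and with unc-119, per the labels. Per the labels' protocols, worms were crosslinked with formaldehyde, chromatin was sonicated and precipitated with goat antibodies against GFP, and size-selected DNA was prepared with Illumina reagents. The labels name 2 replicates, each with 1 ChIP and 1 input library. They do not say whether the replicates came from separate cultures, and the list holds no column per library.

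Per the file headers, coordinates are on WormBase WS180, and the source column names PeakSeq as the caller. Each row of the deposited list gives a region's chromosome, start and end and the authors' q value, which is written in 2 columns that agree for all 7714 regions. The aligner, the read length, the caller's version and settings, the depth of the libraries and the way the replicates were combined are not given in the sources used here. The list has no summits. All listed q values lie under 0.01.

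The q values were taken apart with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. Down the list, every q value equals p × N / (rank + 1), where solving for N gave the whole number 14281. The p values so obtained equal the lower tail of a binomial distribution with probability 0.5, for a pair of whole numbers, at all 7714 regions, with a largest difference of 3.41e-13 in the natural log of p (tolerance 1e-09). A single pair matched at 7710 regions and 2 pairs at 4, which were left out of all values on tags. That the larger number is the ChIP tags and the smaller the scaled input tags rests on knowledge of PeakSeq's test, not on a statement in the list. On each chromosome the smaller numbers fall on the rounded-up multiples of a factor, from 1.32 on IV and 1.33 on I, through 1.57 on X and 1.58 on V, to 1.70 on II and III. Of the regions, 97.9 to 99.7% lie on these values, which take in 58.75 to 75.5% of whole numbers on chromosomes other than IV and 75.75% on IV. Each factor was read as that chromosome's input scaling, and input tags before scaling were obtained by dividing by it and rounding down. Of the regions off these values, 82 in all, 16 have a scaled input of 1 tag.

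Ratios are ChIP over scaled input tags, with 95% exact (Clopper-Pearson) intervals from the ChIP tags and the input tags before scaling; the factor is taken as known. The interval of the median ratio comes from 1000 bootstrap resamples of regions. Input density is input tags before scaling per kb of region width plus 200 bp, for regions of at least 250 bp. The comparisons among regions of at least 1000 bp, for the widest region and for chromosome III, use scaled input tags per kb of width. Chromosome lengths of WS180 were not used here. The fixed plan foresaw counts alone in that case, and the test against the span from the first to the last region was added after the data were seen. Clustering was tested with 10000 uniform placements of the midpoints per chromosome within that span. A second null, added later, shuffles the widths and keeps the shortest gap of 200 bp. A split of each chromosome's input densities into a left and a right part, with at least 40 regions in each, was found by least squares.

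The steps were tested on simulated data. In a simulated list of 2992 regions, the number of tests, 5000, was recovered and 99.97% of the tag pairs were recovered and unique. Of 40 simulated lists placed at random with a shortest gap, 2 had a p under 0.05 in the second null, with a median p of 0.480.

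The named regions are the 10 with the smallest q, by a rule fixed before the data were examined for the case that no annotation of the same build is at hand. The 10 with the highest ratio were added after the values were seen. Planned comparisons of regions with gene starts, gene lists, motifs and the skn-1 and unc-119 loci were not run, because the gene table at hand is on another build and no sequence was used here. Alternatives tried were the best-ranked 3857 and 1928 regions, other distances, leaving out chromosome X, a minimum width of 100 bp, a single input scaling factor and other settings of the density. The recount with a single factor takes the tested regions themselves as unaffected by the scaling.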

Results

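SKN-1 is a transcription factor of the worm Caenorhabditis elegans, known from stress defence and from early gut and muscle specification. Its binding was mapped by chromatin immunoprecipitation and sequencing in hermaphrodite larvae of the first stage (L1) that had been fed at 20 °C. The worms, strain OP178, carried a transgene in which SKN-1 is fused to GFP and other tags, together with a copy of the unc-119 gene. An antibody against GFP pulled down the tagged protein. The design has 2 ChIP libraries and 2 libraries of input chromatin, and it asks which regions of the genome held more ChIP than input DNA. The authors' deposited list combines the libraries, so no value of a single replicate enters any result, and no spread between replicates can be given. The totals of the libraries are not given in the sources used here. All positions are on the WS180 build, and genes near the regions were not analysed here.

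SKN-1::GFP regions were found on all 6 chromosomes, 7714 in total, and most were short. Their median width was 349 bp, with quartiles of 200 and 510 bp, and together they covered 3.33 Mb. The widest region, on chromosome IV, spanned 33885 bp, and the next widest, on chromosome II, 14354 bp. At the other extreme, 1051 regions (13.6%) were under 100 bp wide and 44 were a single base. The authors' q values ran from 2.49e-289 to 0.00993, with a median of 7.17e-05, and 1437 regions had a q under 1e-10. The q values imply 14281 tested regions, of which the listed ones make up 54.02%.

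Enrichment was modest at most regions and high at a minority. The ChIP and scaled input tags recovered from the q values gave a median of 87 ChIP tags against 38 scaled input tags per region. The median ChIP to input ratio was 2.5 (95% bootstrap interval over regions 2.47 to 2.52), with quartiles of 2.03 and 3.22. The ratio was above 2 at 5856 regions (76.0%) and above 4 at 890 (11.5%). The p limit of the list admits regions with few tags only at high ratios, so ratios of narrow and wide regions are not comparable: the 1048 regions under 100 bp with a unique tag pair had a median ratio of 3.63 on 24 ChIP tags, and the 437 regions of at least 1000 bp one of 2.12 on 383 ChIP tags. With input tags as counted, before the scaling to the ChIP libraries, the median ratio was 3.83. The median ratio to scaled input was 2.17 among the 4551 regions with at least 20 input tags before scaling.

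**Figure D1:**
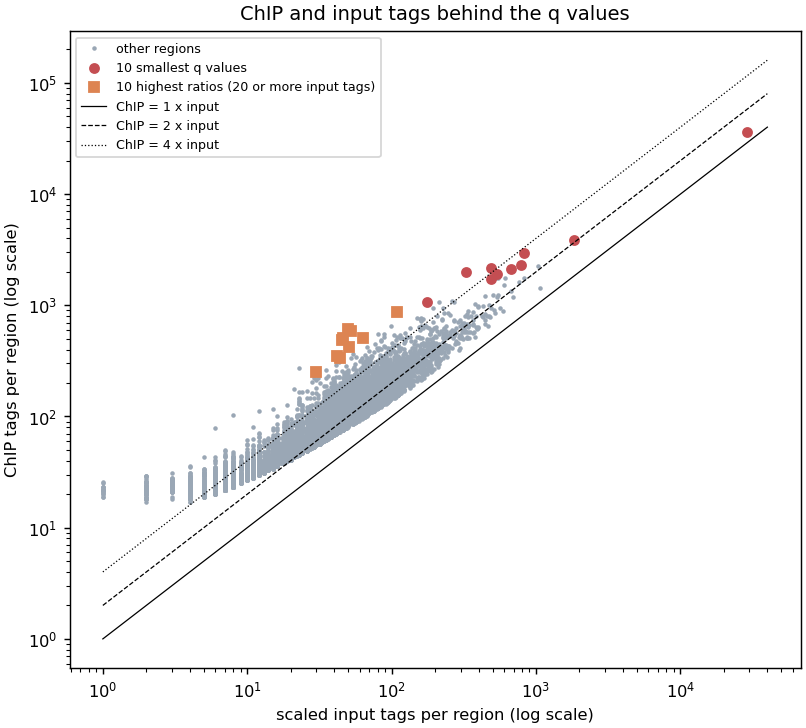
ChIP tags (vertical axis, log scale) against scaled input tags (horizontal axis, log scale) of each region with a unique tag pair; lines mark ratios of 1, 2 and 4. The region at the far right, on chromosome IV, has 36257 ChIP tags against 28959 scaled input tags and lies closest to equal tags.

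The region with the smallest q was on chromosome I at 7595072 to 7598500, with 1998 ChIP tags against 325 scaled input tags. Its ratio was 6.15 (95% exact interval 5.39 to 7.05). The region on chromosome V at 15879982 to 15881855, the last of the 10 with the smallest q, had a similar ratio of 6.03 (4.96 to 7.41) on 1062 ChIP tags. On chromosome X, the region at 1503473 to 1505268 had a ratio of 4.46 (3.96 to 5.04), and the region at 12663018 to 12668857 one of 3.55 (3.17 to 4.01). The first of these lies in a stretch of X where input tags per bp were 1.81-fold those of the rest of the chromosome. The chromosome III regions had ratios of 3.53 (3.21 to 3.90) at 8443236 to 8447557 and 2.92 (2.64 to 3.23) at 9050738 to 9055208. On chromosome I, the region at 12038839 to 12046159 had a ratio of 3.53 (3.16 to 3.96) and that at 7079133 to 7085259 one of 3.14 (2.85 to 3.47). The chromosome II region at 10541846 to 10556199, the second widest of the list, had a ratio of 2.12 (1.98 to 2.27) on 3874 ChIP tags. The intervals cover counting error only.

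The region on chromosome IV at 5642233 to 5676117 had rank 4 by q with the lowest ratio of the list, 1.25 (1.23 to 1.27). It held 36257 ChIP tags and 28959 scaled input tags, or 3.65% and 6.75% of those in all regions with a unique pair. Its input density was 855 scaled tags per kb, against a median of 119.2 and a maximum of 424 in the 436 other regions of at least 1000 bp. Its small q came with a large number of tags and a low ratio.

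**Figure D2:**
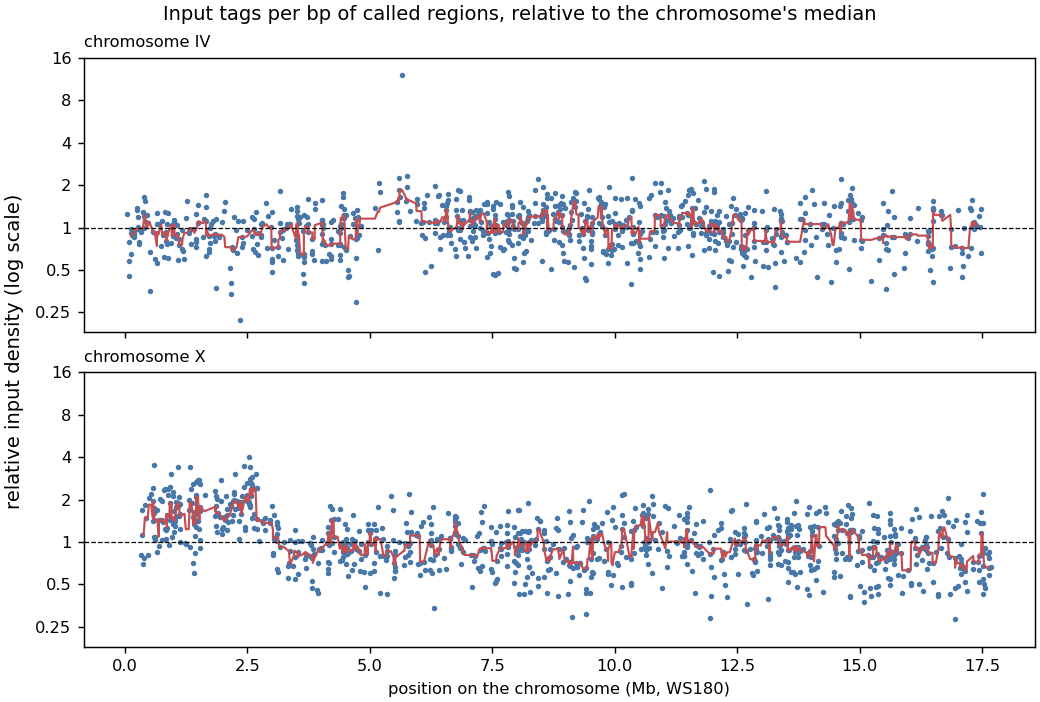
Input tags per bp of each region of at least 250 bp relative to the median of its chromosome (vertical axis, log scale) along chromosomes IV and X (horizontal axis, Mb on WS180); the red line is a running median over 9 regions. The region at 5642233 stands alone on IV, and regions up to 2997469 on X have a median 1.81-fold that of the rest of X.

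The highest ratios belonged to other, narrower regions. Among regions with at least 20 input tags before scaling, a minimum chosen after the data were seen, the 10 highest ratios ran from 7.59 to 12.1 at widths of 475 to 1199 bp. None of these 10 was among the 10 with the smallest q, and their ranks by q ran from 12 to 127. The region on chromosome I at 1048989 to 1049953 led with 606 ChIP tags against 50 scaled input tags (ratio 12.1, 8.86 to 17.7). It was followed by chromosome II at 10949860 to 10950434 (11.2, 7.91 to 17.1), chromosome X at 1420263 to 1420926 (10.98, 7.64 to 16.8) and chromosome V at 18614356 to 18615032 (10.8, 7.52 to 16.7). The intervals of these 4 overlap, so their order was not resolved at this depth, and ratios picked as the highest tend to lie above their true values. The order also rests on the scaling factors inferred per chromosome, which the intervals take as known. Before scaling, the chromosome I region had 37 input tags to 606 ChIP tags, and the chromosome II region 30 to 584. The X region of these 4 lies in the stretch of high input density named above. Chromosome V had a further region at 2057299 to 2057773 (8.31, 5.68 to 13.2), and chromosome I one at 3908430 to 3908930 (7.59, 5.33 to 11.3). Chromosome IV had 4: 1094067 to 1094570 (8.30, 5.54 to 13.9), 1709573 to 1710387 (8.27, 6.03 to 12.1), 6909904 to 6910487 (8.11, 6.10 to 11.4) and 4215238 to 4216436 (8.04, 6.45 to 10.3).

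**Figure D3:**
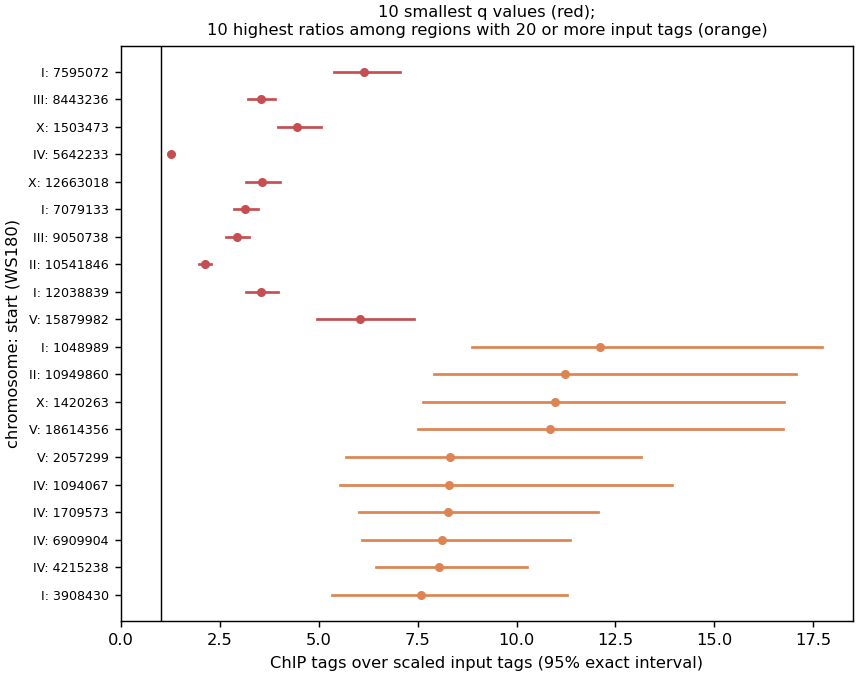
ChIP to scaled input tag ratio (horizontal axis) of the 10 regions with the smallest q (red) and the 10 with the highest ratio among regions with at least 20 input tags before scaling (orange), by chromosome and start; bars are 95% exact intervals for counting error and the vertical line marks a ratio of 1. The chromosome IV region at 5642233, with a ratio of 1.25, lies below the others.

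Regions were densest on chromosome I and sparsest on chromosome V. Chromosome I held 1502 regions, or 100 per Mb of the span from its first to its last region, 29.9% above the 77.2 per Mb of all chromosomes together. Chromosome V held 1223, or 58.6 per Mb, a difference of -24.1%. Chromosome II, with 1040 regions and 68.2 per Mb, differed by -11.7%. Chromosomes III (1125 regions, 81.8 per Mb), IV (1408, 80.8 per Mb) and X (1416, 80.5 per Mb) did not pass the test in the full list. The counts differed from those expected by span, in a test chosen after the data were seen (chi-square 222 on 5 degrees of freedom, p = 5.08e-46). The exact binomial tests, two-sided and Benjamini-Hochberg adjusted over the 6 chromosomes, gave p = 6.65e-26 for I, 1.61e-28 for V and 2.00e-05 for II, and 0.0608, 0.0807 and 0.0913 for III, IV and X. Regions cluster, so these p values are too small. The input scaling inferred for each chromosome bears on the ranking: with the highest factor used on every chromosome, 6545 regions pass the same p limit, and chromosome III (81.6 per Mb) stands above chromosome I (73.8 per Mb). In that recount III has the largest excess over the mean, 24.5% (adjusted exact p = 5.26e-14), and I stays above and V below it, by 12.6% and -21.2%. X passes at 5.96% (exact p = 0.0315), IV turns from 4.56% to -14.4% (p = 1.06e-07), and II turns to 4.08% (p = 0.164). The recount can only take regions from chromosomes of lower factor: II kept 100% and III 99.7% of its regions, I 73.6% and IV 69.5%. The rise of II and III and the fall of IV were thus built in, though not their sizes. Their p values in this recount are therefore not separate evidence. The calls of III and IV also change elsewhere: III passes in the best-ranked 3857 regions, at 11.4% (exact p = 0.00757), and both pass without the left end of X, at 6.44% (p = 0.0375) and 5.11% (p = 0.0482).

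**Figure D4:**
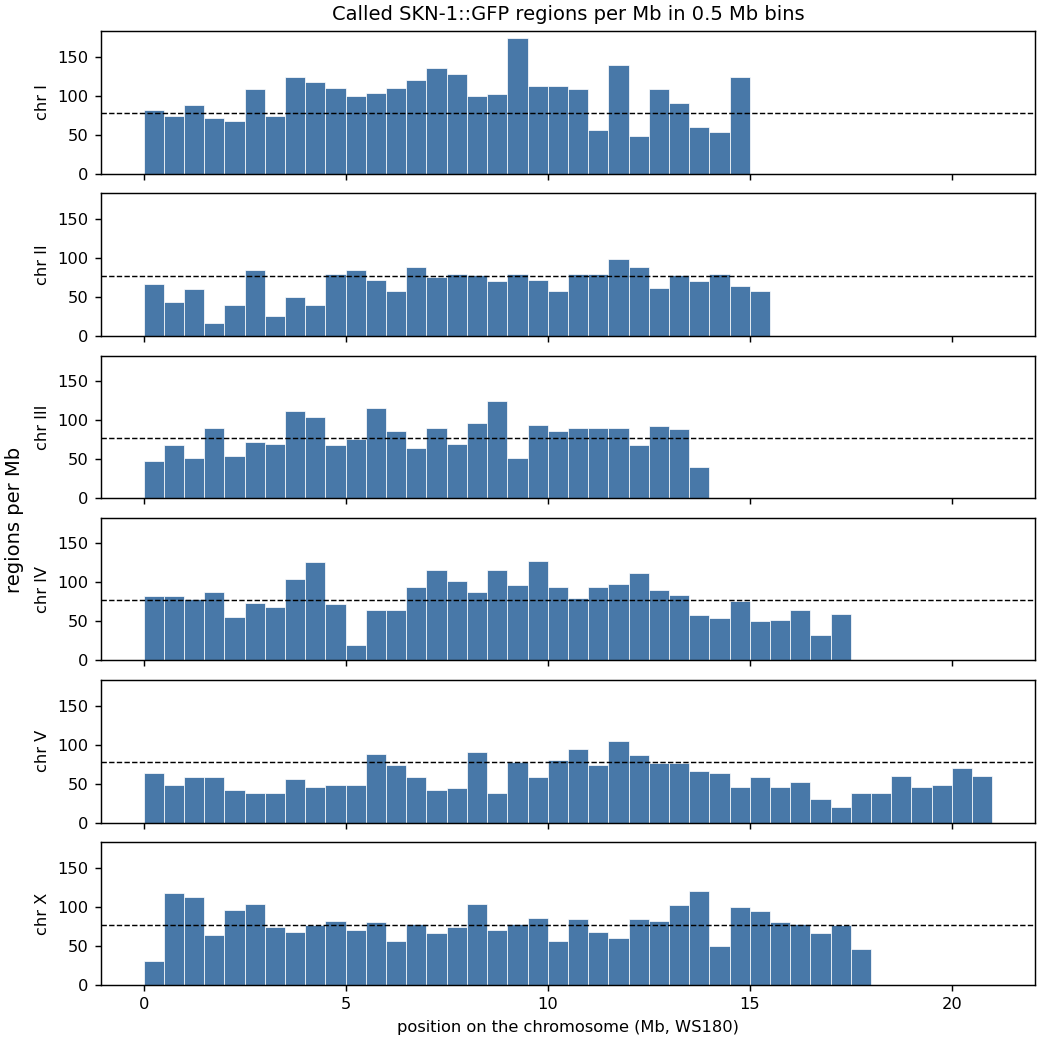
Called regions per Mb (vertical axis) in bins of 0.5 Mb along each chromosome (horizontal axis, Mb on WS180); the dashed line is the mean of 77.2 per Mb, and the last bin of a chromosome is only partly covered by it. Most bins of chromosome I lie above the mean and most bins of chromosome V below it.

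Within chromosomes, both ends were sparse in regions on I and V, 1 end was sparse on II, III and IV, and both ends of X held slightly more than an even share. The central 50% of the span held 58.6% of the regions of V, 58.3% of those of I, 56.3% of IV, 54.04% of III and 53.4% of II, and 46.9% of those of X. Each share differed from 50% by an exact binomial test, with adjusted p from 1.01e-09 for I to 0.0323 for II and 0.0249 for X. These p values are too small as well, since regions cluster, and in the full list the calls of II and X lie near the threshold. This split was chosen after the data were seen, and for II and III it did not pass in the best-ranked 1928 regions, nor for II in the best-ranked 3857. For X the central share was lower in the stricter lists. It was 42.9% in the best-ranked 3857 regions and 39.6% in the best-ranked 1928 (unadjusted exact binomial p = 0.000301 and 0.000185). The stretch of high input density named above lies at the left end of X, outside the central part. Its ChIP tags per kb were 1.77-fold those of the rest of X. It held 12 of the 100 regions with the smallest q. More tags give a smaller q at an equal ratio, so ranking by q can by itself lower the central share. No stricter list without this stretch was tried, so how much of the fall comes from it was not tested. On I the first 25% of the span held 20.5% of the regions and the last 21.2%, and on V 21.4% and 19.95%. On II the shares rose along the chromosome, from 17.3% in the first 25% of the span to 29.3% in the last, its densest part, and on III the first held 19.9% and the last 26.04%. On IV the first held 25.9% and the last 17.8%, and on X 26.4% and 26.7%. These shares of the ends were not tested. The densest windows of 100 kb were on chromosome I at 7000001 to 7100000, with 23 regions, and on chromosomes I at 11600001 to 11700000 and X at 2500001 to 2600000, with 22 each, against a mean of 7.72. The X window lies in the stretch of high input density named above. The longest stretches without a region were on chromosome V at 17380130 to 17715728 (336 kb), chromosome II at 1504561 to 1816492 (312 kb) and chromosome V at 2290587 to 2588037 (297 kb).

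The regions lay closer together than uniform placement gives. Another region's midpoint lay within 2 kb of 2751 regions (35.7%), against a mean of 27.1% in 10000 uniform placements and a highest of 29.7% (one-sided permutation p = 0.0001, the smallest these placements can give). Within 5 kb the share was 65.3% against 54.4% (permutation p = 0.0001). Within 1 kb it was 12.98% against 14.7%, the opposite direction. No 2 listed regions are less than 200 bp apart, and when the placements keep the widths and that shortest gap, a null chosen after the 1 kb result was seen, 12.98% stands against 6.54% (permutation p = 0.0001). In the best-ranked 1928 regions the share within 2 kb was 8.35% against 7.83% in uniform placements (permutation p = 0.276), and against 4.36% in placements that keep the widths and the shortest gap (permutation p = 0.0001). Within 1 kb these 1928 regions did not pass under that null, at 0.934% against 0.758% (permutation p = 0.304). Both nulls place regions evenly along each span, although density varied along chromosomes, which by itself raises the share with a neighbour. How much of the excess comes from that was not tested. Whether neighbouring regions are pieces of a broader enriched region was not tested either.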

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

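The stricter lists, the other distances of 1 and 5 kb and leaving out chromosome X were planned as alternatives; the chromosome test against span that some of them apply to, the single scaling factor, the count without the left end of X, the null with the shortest gap, the minimum width, and every alternative for the ratio, the central share and the left end of X were chosen after the data were seen. Of 68 alternatives, 46 kept direction and side of the threshold, stayed in their interval or, for a count of regions, within 1.5 times, 7 moved, 5 turned direction, 5 no longer passed and 5 newly passed. No paired analysis was possible because the combined list holds no values per library, although ChIP and input share replicate numbers 1 and 2; for the same reason no replicate could be left out. Stricter lists hold 3857 and 1928 regions by construction. The 5 that newly passed were chromosome III in the best-ranked 3857 regions (11.4%, adjusted exact p = 0.00757), III and IV without the left end of X (p = 0.0375 and 0.0482), and III and X with a single scaling factor (24.5%, p = 5.26e-14, and 5.96%, p = 0.0315). Chromosome II no longer passed in the best-ranked 1928 regions (-9.97%, exact p = 0.132). With a single scaling factor chromosome II moved from -11.7% to 4.08% and IV from 4.56% to -14.4%, as fewer regions pass on chromosomes of low factor. The rise of II and III and the fall of IV were built into that recount, so its calls of III and IV are not separate evidence. X, not called at 4.17%, stood at -2.30% and -1.98% in the 3857 and 1928 best-ranked regions, and the cause was not tested. Clustering within 1 kb fell below uniform placement, 12.98% against 14.7%, where region widths and the shortest gap of 200 bp both keep midpoints apart; the share of each was not tested. Within 2 kb the best-ranked 1928 regions gave 8.35% against 7.83% in uniform placements (permutation p = 0.276). The same regions passed against 4.36% in placements that keep the widths and the shortest gap (permutation p = 0.0001), so this call depends on the null. The median ratio was 2.64 and 2.90 in the stricter lists, 3.83 without input scaling and 2.17 with at least 20 input tags. The input density of the left end of X was 1.64-fold in the best-ranked 1928 regions, and the cause was not tested. Low tag numbers limit narrow regions most: under 100 bp the median was 24 ChIP tags.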

Other observations

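Chosen after the result was seen were the comparison of input density at the widest region, the test of extra copies at the left end of X and the test of the ratio of the widest region; the comparison of that ratio was also narrowed to regions with many input tags after a first version had been run. The tests of chromosome III, of the scaling on I, of the other chromosome ends and of region width were written before their results were seen.

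The left end of chromosome X stood apart in its input. Regions of at least 250 bp up to 2997469 had a median of 91.8 input tags per kb before scaling, against 50.7 in the rest of X. The difference was 1.81-fold (95% bootstrap interval 1.66 to 1.98, with 179 and 808 regions). The edge was chosen on the same values and neighbouring regions are not independent, so the interval is too narrow; a test that rotated the values along X was also run and left out, as it cannot allow for that choice. On the other 5 chromosomes the best split gave a fold between 0.786 and 1.26. ChIP tags per kb were 1.77-fold higher in the stretch, which also held 12 of the 100 regions with the smallest q. Counting regions of any width from 117173, the start of the first, it held 91.0 regions per Mb, against 78.4 in the rest of X. That length includes a gap of 205 kb without a region, from 117313 to 322309.

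A general effect of chromosome ends is argued against by the other 11 ends, none of which lay above the rest of its chromosome (highest log2 difference -0.0441, on the right of IV). Wider or stronger regions are argued against for width, since regions of 300 to 500 bp kept a log2 difference of 0.83. Extra copies of this stretch in the strain, which both kinds of library would carry, stay open. The ChIP to input ratio in the stretch was 0.889 times that of the rest of X. That ratio cannot tell extra copies from raised input alone, because every listed region had to pass a limit of ChIP over input. More open chromatin at these regions stays open, since input between called regions was not analysed here. Apart from the comparison for extra copies, no biological explanation was tested.

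The widest region, on chromosome IV, stood out by its 855 scaled input tags per kb, against at most 424 in the 436 other regions of at least 1000 bp. Its ratio of 1.25 (1.23 to 1.27) lay below the 5th percentile of 1.503 in the 80 other regions with at least 300 scaled input tags. It also lay below the 1.64 of all other regions, many of which could not be listed at so low a ratio. As the lowest ratio of the list it had to fall below both. The comparison therefore cannot argue against enrichment like that of other regions. The ratio is also an average over 33885 bp, so enrichment in parts of this region stays open. The 9 other regions within 100 kb of its middle had 1.65 times the chromosome's median input density. Extra copies of skn-1, a gene of that chromosome, in the bombarded transgene and a sequence repeated in the genome both stay open, since the high density that singled the region out cannot count for either and no sequence was used here. For unc-119, the transgene's other gene, on chromosome III, the highest value there was 243 scaled input tags per kb. The prediction had counted such a value against extra copies, which was wrong by design. Of the tested regions, 6567 are not listed, and extra copies without enrichment could be among them or in no tested region.

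The lead of chromosome I in regions per Mb depends on the input scaling factors. With the highest factor on every chromosome it had 73.8 regions per Mb, below the 81.6 of III. Such a recount can only take regions from chromosomes of lower factor, so a fall of I was built in, though not its size. Chromosome IV, with a factor of 1.32 against 1.33 on I, had 80.8 regions per Mb in the full list and no such lead. In the recount I stayed 12.6% above the mean. The recount takes the tested regions as unaffected by the scaling, so it cannot say how much of the excess the factor accounts for. Whether the factors follow real differences in background between chromosomes was not tested, and no biological explanation was tested.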
